A study of Mus musculus with 16 samples.

How the data were processed

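RNA was measured in 16 libraries of purified mouse CD4 T cells from animals with Rosa26-CreERT2 and floxed Sin3a alleles, about 2 months old, on a C57BL/6J background. Per the labels' protocols, cells were kept for 6 days in IL-7 with or without tamoxifen, and part of them went through 3 further days of Th17 polarization. Poly(A) RNA, about 100 ng per library, was turned into stranded libraries and sequenced on a NextSeq2000 for 59 cycles, per the labels. Groups and numbers came from the sample labels: IL-7 sufficient, IL-7 deficient, Th17 sufficient and Th17 deficient, with 4 libraries each. The labels give 1 of the 4 recurring numbers as female and 3 as male, and do not say that a number stands for a mouse. A library treated with tamoxifen that lacks the floxed alleles was not analysed here (0 libraries), so deletion and tamoxifen go together in every comparison of deficient with sufficient cells.

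Per the submitters' processing notes, reads were trimmed with Trim Galore 0.4.4, aligned with STAR 2.6 to mouse build NCBIM37 and counted per gene with featureCounts, and edgeR and DESeq2 were used. The settings of these steps are not given in the sources used here. No coordinates are given, because the reference at hand is of another build. The deposited data are a single table. Per the file headers it holds, for 8552 named genes, the authors' own comparison with a mean normalized count, a log2 fold change with its standard error, a test statistic, a p-value and an adjusted p-value. Beside these stand 16 columns of normalized counts, 1 per library. The authors' log2 fold changes are all below 0 and compare deficient with sufficient Th17 cells. The authors' p-value belongs to a test statistic, a score on the scale of the fold change over its standard error. Adjusted p-values under 0.05 stand beside 4366 genes in the authors' deposited table, of which 1944 have a log2 fold change of -1 or lower. The authors' mean normalized count implies about 24 libraries behind it, and 16 are analysed here.

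The deposited normalized counts, which are counts divided by the authors' size factor of each library, had lost their decimal points, and their lines were not in the order of the gene names. Each library's values are whole reads times 1 step, so the digits give the reads up to a power of 10. The step was found per library, and 99.993% of nonzero values were whole multiples of it. The power of 10 was set by the agreement of the 4 libraries of a group, and 8.61% of nonzero values were raised. A table row counted as settled where the posterior of its powers was at least 0.95 in every group, with a stricter limit where 3 of 4 libraries needed a raise. In rows joined to a gene name, as described below, the Th17 groups counted as settled by the join. Only their IL-7 groups had to reach these limits. In all 15239 rows were settled (85.4%) and 2611 were not, 35 of them by the stricter limit. A gene name was joined to the row whose reads gave the authors' log2 fold change at the dispersion that their standard error implies. The difference had to be at most 1e-06, and the next row had to differ 20 times more. Names were joined for 8097 genes (94.7%), 380 of them on next-best powers of 10, and 455 were not joined. Of 1000 decoys, genes whose fold change had been shifted slightly, 2 were joined. The decoys were searched only on the final powers of 10 and not over next-best powers. Their share therefore does not cover the step that gave the 380 joins.

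The restoring was tested on simulated data with known answers, where 97.3% of the sets of 4 values in a group were exact. Of the settled rows 98.7% were exact, and 999 of 1000 genes were joined to the right row and 1 to a wrong one. The simulated reads were drawn around the restored values at 1 fixed dispersion, so an error already made there counted as right. Settled rows were 73.4% in the simulation and 85.4% in the data, so these shares do not measure the error of the real restoring. Unsettled rows were more frequent without a name (18.9%) than with one (9.51%), and at mean counts of 10 to 100 the shares were 38.5% and 19.5%. This gap follows in part from the rule, since the join itself settled the Th17 groups of named rows. The restriction to settled rows therefore favours named rows, which the authors list as lower. The way of setting the powers, the restriction to settled rows and the stricter limit were chosen after first results had been seen. The stricter limit was eased once because its first form removed Sin3a. Rows without a name enter the counts of called rows, the scaling, the principal components, the correlation and overlap of the deletion effects, the choice of polarization genes and the comparison of rows by level, and no single such row is described. Restored totals were 19752393 to 28630835 reads per library, fewer than the number stated in the labels, and these set the precision of low genes. A total covers only the rows of the table.

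The comparisons, tests, gene lists, naming rule and a first set of alternatives were fixed before the data were examined. That design assumed raw counts and a quasi-likelihood test for counts. The values turned out to be normalized counts, with reads restored only through inferred powers of 10. No count test was run on these reads, and limma 3.58.1 in R 4.3.3 was used with a mean-variance trend on log2(normalized count + 1). The pseudocount of 1 makes the change of low genes smaller than it is. Rows needed at least 10 normalized counts in at least 4 libraries, which left 14638 tested rows, 7007 of them named. The 4 groups formed 1 factor over all 16 libraries without a block, and p-values were two-sided and adjusted by the Benjamini-Hochberg method over all tested rows at 0.05. The comparisons were deficient against sufficient cells at each stage, Th17 against IL-7 cells in each genotype, and the interaction. On simulated data the test found 45 of 100 genes changed 1.5-fold and 69 of 100 changed 2-fold in the IL-7 comparison (14577 rows, 2 of 116 calls false). It found 49 and 78 of 100 in the Th17 comparison (14729 rows, 5 of 132 calls false).

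Of the 27 gene lists, 262 of 489 members stand in the authors' table and 241 were joined to a row, so each list covers only members that the authors list as lower. They were the Sin3 complex, Th17, Th1, Th2, regulatory T cell, naive and quiescent, IL-2 and STAT5, IL-6 and TGF-β, T cell activation, cell cycle, kinase inhibitor, p53 target, Bcl2 family, glycolysis, oxidative phosphorylation, cholesterol, interferon, amino acid stress, heat shock, neuronal, germline, T cell identity, B cell, myeloid, NK, CD8 and erythroid lists. Ribosomal protein and mitochondrial genes were 2 more. Lists with at least 3 tested members were set against the other named rows with camera of limma at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with an estimated correlation. The named genes are a fixed set, the genes with the largest changes (10 per direction, or 6 for Th17 against IL-7 in deficient cells and for the interaction) that passed the test at a mean CPM of at least 2 without overlap of the groups (no such demand for the interaction), and up to 4 called members per list. Some genes that this rule names are not reported here. Of the fixed set, Sin3b, Foxp3, Tbx21 and Mki67 are not analysed here. Il4, Il23r, Ifng, Il2, Stat3 and Cdkn1a had unsettled values and were not tested.

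For the polarization genes, rows that changed at least 2-fold over polarization in sufficient libraries of 2 numbers were measured in the libraries of the other numbers. Shares of reads were compared by two-sided exact permutation tests, 4 against 4. Alternatives were a block on the library number, library totals, other filters, other pseudocounts, voom weights on the restored reads and library weights. Median-of-ratios size factors were also recomputed on the tested rows with reads in every library. Further alternatives were fits on 8 libraries, unsettled rows kept, and leaving out each library or each number. No pair of replicates was identical, and the chi-square per row over 12069 rows lay between 6.37 and 83.0 in the 24 pairs within groups, where sampling alone gives 1. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the restoring and the figures.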

Results

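Poly(A) RNA was sequenced from purified CD4 T cells of mice that carry a tamoxifen-activated Cre recombinase (Rosa26-CreERT2) and floxed alleles of Sin3a. Sin3a encodes Sin3A, the scaffold of a histone deacetylase corepressor complex. Cells were kept for 6 days in the survival cytokine IL-7, with tamoxifen to delete Sin3a (Sin3A deficient) or without it (Sin3A sufficient). Part of each culture type was then polarized for 3 days towards Th17 cells, the helper T cells that make IL-17. The 4 groups held 4 libraries each, and restored totals ran from 19752393 to 28630835 reads per library. The library names, such as BASAL957 (IL-7, sufficient), BASALTAM957 (IL-7, deficient), D3957 (Th17, sufficient) and D3TAM957 (Th17, deficient), end in one of 4 numbers that recur in every group. Gene names could be joined only to genes that the authors' deposited table lists as lower in deficient Th17 cells, so genes higher there appear as counts of unnamed rows. The labels do not say that libraries came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

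The targeted gene was examined first. Sin3a (ENSMUSG00000042557) stood at 2524 ± 249 normalized counts in sufficient and 2211 ± 98.2 in deficient IL-7 cells (mean ± SD, n = 4 each). After polarization the levels were 2106 ± 181 and 1774 ± 49.8 (n = 4 each), and all 4 deficient libraries lay below all 4 sufficient ones. The log2 change was -0.24 with an SE of 0.08 in Th17 cells (limma adjusted p = 0.0116), a small fall. In IL-7 cells it was -0.19 with an SE of 0.08, which did not pass the test (limma adjusted p = 0.188). The difference between both effects, -0.06, did not pass either (limma adjusted p = 0.713). Without the 4 libraries that carry the number of BASAL957 the Th17 change was -0.21 and no longer passed (limma adjusted p = 0.0961). The labels do not name the floxed exons, so the total for the gene need not follow the deletion, and 3 of the 4 Sin3a values in deficient IL-7 cells had to be raised by a power of 10 in restoring the lost decimal points.

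**Figure D1:**
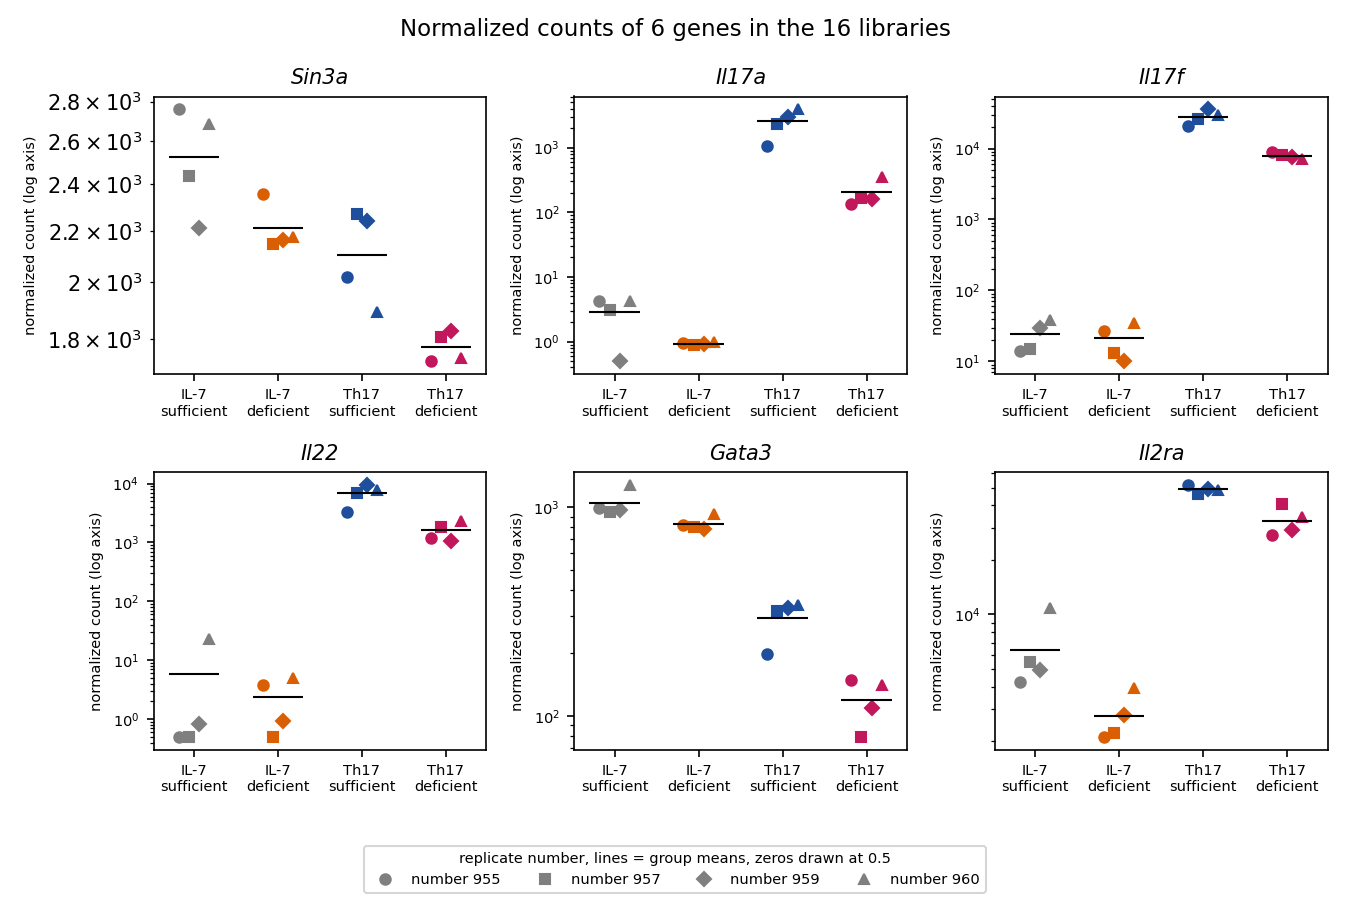
Normalized counts on log axes of Sin3a, Il17a, Il17f, Il22, Gata3 and Il2ra in the 16 libraries, by group, with markers for the replicate number and lines at the group means. Il17f averaged 7910 in deficient Th17 cells, and every one of those 4 libraries lay below the sufficient ones.

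**Figure D2:**
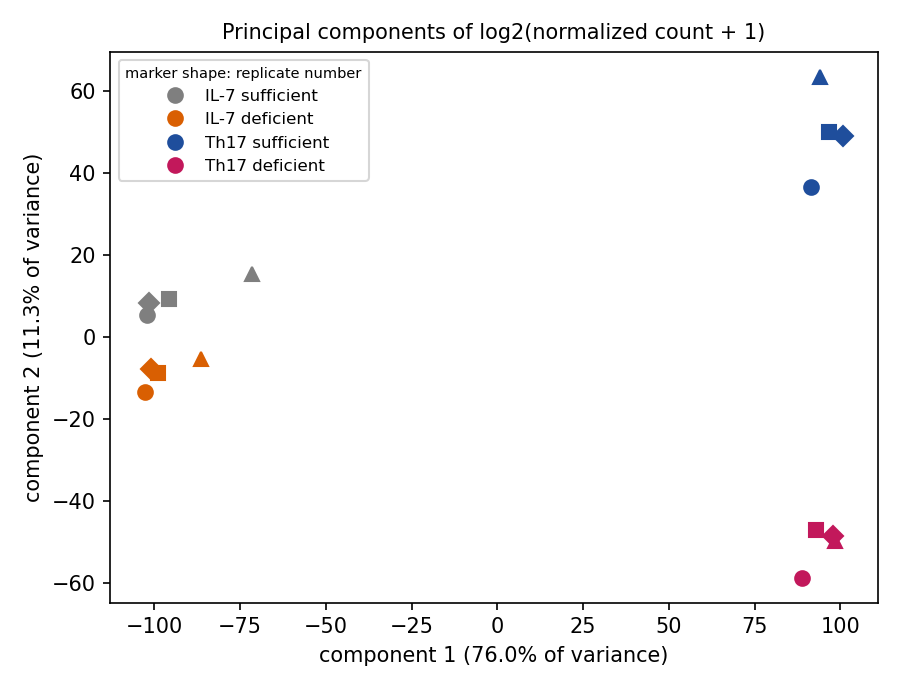
Principal components of log2(normalized count + 1), with component 1 on the horizontal axis (76.0% of the variance) and component 2 on the vertical axis (11.3%), coloured by group and shaped by replicate number. Polarized and unpolarized libraries separate along component 1, and deficient and sufficient Th17 libraries along component 2. The IL-7 libraries also separate along component 2 in the same direction, with sufficient ones at 5.47 to 15.4 and deficient ones at -13.3 to -5.20.

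Sin3A-deficient and sufficient cells were compared after 3 days of Th17 polarization, the comparison that the series design names. Of the cytokine genes of Th17 cells, Il17a, Il17f and Il22 fell in deficient cells, while Il21 did not pass (log2 change -0.47, limma adjusted p = 0.379). Il17a, which encodes IL-17A, went from 2557 ± 1201 to 203 ± 98.9 normalized counts (n = 4 each), a log2 change of -3.60 with an SE of 0.47 (limma adjusted p = 5.6e-06). Il17f, encoding IL-17F, fell from 28001 ± 6433 to 7910 ± 779 (n = 4 each, log2 change -1.80, SE 0.33, limma adjusted p = 0.00019). Il22, encoding the epithelial cytokine IL-22, changed by -2.08 with an SE of 0.78 (limma adjusted p = 0.031).

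Genes of other effector and inhibitory functions were lower in deficient Th17 cells as well. All 8 tested members of the regulatory T cell list fell, among them the inhibitory receptors Tigit (log2 change -3.03) and Ctla4 (-1.72) and the TNF receptor family member Tnfrsf18 (-1.72). Over all tested named genes 3777 of 7007 fell and 0 rose, because only genes listed as lower carry names. List counts near that share show no more than this choice of names. Members that the authors do not list as lower could not be tested. Listed were 7 of 22 naive and quiescent, 10 of 16 regulatory T cell, 18 of 38 cell cycle and 8 of 24 Sin3 complex members. Over all lists 262 of 489 were listed, so the counts do not describe whole lists. Of the 14 tested members of the Th17 list, 8 fell, led by Tgfb3, a TGF-β cytokine gene, at -4.67. T cell activation genes fell in 9 of 11 cases, with Tnfrsf9 (4-1BB) at -2.54, the AP-1 factor Fosl2 at -1.87 and Tnfrsf4 (OX40) at -1.74. In the naive and quiescent list 6 of 7 fell, including Pecam1 (CD31) at -2.25, the chromatin organizer Satb1 at -1.09 and the survival gene Bcl2 at -1.05. In the Th2 list 3 of 4 fell, with the Th2 transcription factor Gata3 at -1.31 (SE 0.19), and in the Th1 list 4 of 7, with Stat4, which acts downstream of IL-12, at -1.19 and Runx3 at -0.53. The interferon list had 9 of 16 members lower, among them the antiviral sensor gene Oas3 at -2.29. All 4 tested genes of cyclin-dependent kinase inhibitors fell, with Cdkn1b (p27) at -1.05, while cell cycle genes fell in 1 of 9 cases, Cenpa at -0.56.

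Metabolic and structural lists were lower in part as well. Glycolysis genes fell in 12 of 16 cases, such as Gapdh (-0.96), the glucose transporter Slc2a1 (-0.86) and Tpi1 (-0.80). Cholesterol synthesis genes fell in 8 of 12. Amino acid stress genes fell in 6 of 8, with Ddit4, an inhibitor of mTORC1 signalling, at -1.61 and Trib3 at -1.50. In the list of T cell identity 10 of 11 fell, including the CD3 chain gene Cd3d (-0.97) and Thy1 (-0.85). Of the Sin3 complex list 6 of 8 fell, with Tet1, a 5-methylcytosine oxidase, at -1.94 and the histone demethylase Kdm5a at -0.70. The widest falls among genes passing the naming rule were Dhdh (-4.87), Tgfb3, Asb16 (-4.46), Sncb, encoding β-synuclein (-4.43), Cntnap1 (-4.31), the Wnt pathway receptor gene Kremen2 (-4.23) and the class I gene H2-Q10 (-4.07). Reads of H2-Q10 can be shared with related class I genes.

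**Figure D3:**
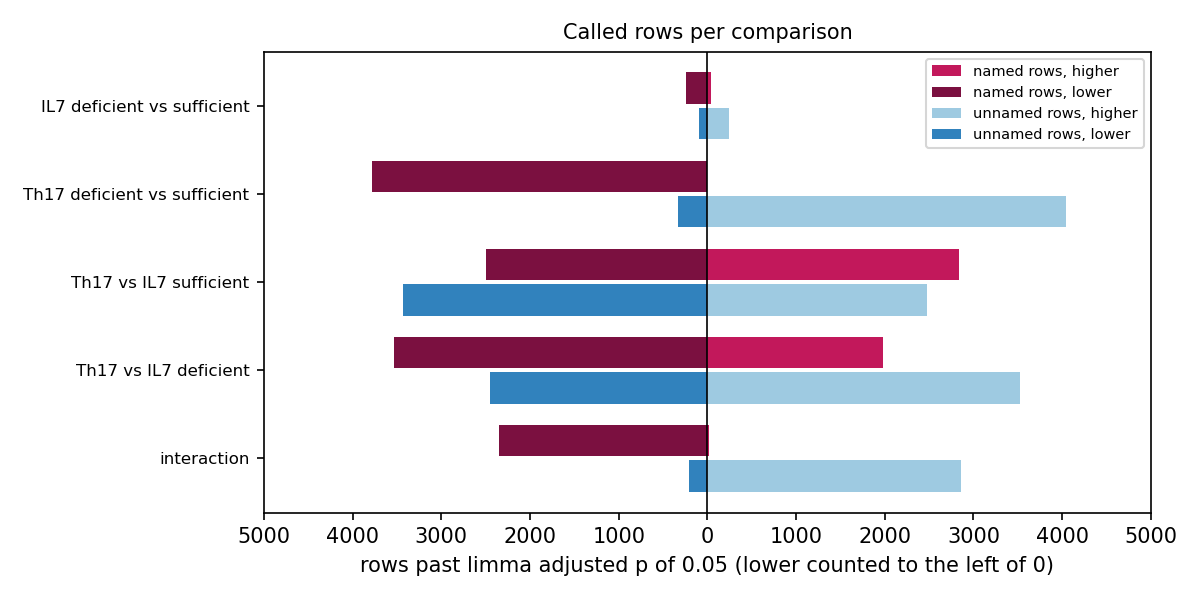
Number of table rows past a limma adjusted p of 0.05 in each comparison, with rows that were lower counted to the left of 0 and higher to the right, for named and unnamed rows. In deficient Th17 cells 3777 named rows were lower and 0 higher, and 4042 unnamed rows were higher.

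In total 8149 of 14638 tested rows passed a limma adjusted p of 0.05 in this comparison, 4042 higher and 4107 lower in deficient cells. At 2-fold or more, 885 were higher and 1566 lower. The 3777 named genes among them were all lower because the deposited list holds falls in these same libraries, so these list counts are not independent evidence of direction. Adjusted over the list alone, the counts differed for the Th2 list (4), the Th1 list (5) and glycolysis (14), and were equal for the other lists given above. Set against the other named genes, the T cell identity list lay lower (limma camera adjusted p = 0.00244) and cell cycle genes lay higher, at a median of -0.19 (limma camera adjusted p = 0.0395). With an estimated correlation neither passed (adjusted p = 0.62 and adjusted p = 0.741). Il22 did not pass without the number of BASAL957 (-2.13, limma adjusted p = 0.0679) or of BASAL959 (-1.71, limma adjusted p = 0.181), and with a pseudocount of 0.5 it did not either (limma adjusted p = 0.0715). With 1 library left out it did not pass without D3957, D3959, D3960, D3TAM955 or D3TAM959 (limma adjusted p from 0.0602 to 0.0763).

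The same deletion was then examined in cells kept in IL-7 without polarization, where fewer genes changed. Genes of the IL-2 and STAT5 group fell in 5 of 12 cases (9 adjusted over the list alone), including Il2ra, the high-affinity IL-2 receptor chain (log2 change -1.15, SE 0.23, limma adjusted p = 0.00959), the feedback inhibitor Cish (-0.82) and the kinase gene Pim1 (-0.64). Il2ra stood at 6361 ± 3009 in sufficient and 2759 ± 840 in deficient cells (n = 4 each). Of the regulatory T cell list 4 of 8 fell (5 adjusted over the list alone), with the integrin gene Itgae (CD103) at -1.91 and Ctla4 at -0.78. The Ctla4 and Pim1 calls were lost in 16 and 13 of 31 alternatives. Of these alternatives, 11 and 10 left out 1 library. Of the Th17 list 1 of 14 members fell (5 adjusted over the list alone). Among the larger falls were Blk, a Src family kinase gene of B cells (-2.50), Gpr97, an adhesion receptor gene (-2.12), Pigz, a GPI anchor enzyme gene (-2.11), Ifitm3, an antiviral membrane protein gene (-2.11), Neb, encoding nebulin (-1.71), and Gadd45g (-1.70). The largest rises among genes passing the naming rule were Fam221a (1.44), Katnal1, a microtubule severing gene (0.74), Spef2 (0.69) and the ATP receptor gene P2rx4 (0.63).

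Other lists held fewer calls in IL-7 cells. Of the T cell activation list 2 of 11 fell, Il2ra and the costimulatory receptor gene Icos (-0.92), and of the cell cycle list 2 of 9, Ube2c (-1.57) and Cenpa (-0.57). Adjusted over the list alone these were 6 and 4. The Ube2c call was lost in 19 of 31 alternatives, 13 of them with 1 library left out. Single members fell in the Th1 list (Il18r1, -0.90), the Th2 list (Il4ra, -0.79), the kinase inhibitor list (Cdkn2a, -2.77), the Bcl2 family (Bak1, -0.47), the germline list (Tdrkh, -0.56) and the B cell list (Blk). In the interferon list 0 of 16 members passed in limma, with 10 at an unadjusted p under 0.05 and a median log2 change of -1.03. Gata3 (-0.32, limma adjusted p = 0.394) and Il17f (-0.22, limma adjusted p = 0.796) did not pass, and Il17a and Il22 averaged under 6 normalized counts in both groups, with Il22 at 22.8 in BASAL960 and under 1 in the other sufficient libraries.

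In IL-7 cells 614 of 14638 rows passed a limma adjusted p of 0.05, 282 higher and 332 lower, of which 43 and 240 carried names. Against the other named genes, members lay lower in the lists of IL-2 and STAT5 (limma camera adjusted p = 1.8e-05), regulatory T cells (8.1e-05), interferon (0.00043), cell cycle (0.00144), T cell activation (0.00149), Th17 (0.00697) and germline genes (0.0458). None passed with an estimated correlation (each adjusted p = 0.62). The sufficient IL-7 library BASAL960 stood apart, and without it the medians moved from -1.03 to -0.34 for interferon, from -0.58 to -0.44 for IL-2 and STAT5, from -0.67 to -0.60 for regulatory T cells, from -0.53 to -0.35 for Th17 and from -0.57 to -0.35 for cell cycle genes. Without all 4 libraries of that number the medians were -0.32, -0.45, -0.66, -0.48 and -0.57 in the same order, so the Th17 and cell cycle medians then moved little. Without BASAL960 alone the called members went from 5 to 3 for IL-2 and STAT5, from 4 to 2 for regulatory T cells and from 2 to 1 for cell cycle genes, and Cdkn2a and Bak1 did not pass. Such losses were not particular to BASAL960. Over the fits with 1 library left out, Bak1 did not pass in 11, Cdkn2a in 4 and the cell cycle gene Ube2c in 13. The 3 named rows of the mitochondrial genome took 0.526% ± 0.0682 of reads in sufficient and 0.733% ± 0.102 in deficient IL-7 cells (n = 4 each). Mitochondrial genes without a name are not in this share.

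The IL-7 count depended on single libraries. It was 30 without the 4 libraries that carry the number of BASAL957 and 114 without those with the number of BASAL959. Leaving out 1 library gave 328 without BASAL957, 304 without BASALTAM955, 237 without BASALTAM957 and 362 without BASALTAM959. Called members of the IL-2 and STAT5 and the regulatory T cell lists were 3 and 2 without any 1 of BASAL957, BASALTAM955, BASALTAM957 and BASALTAM959, and regulatory T cell calls were also 2 without D3957 or D3TAM959. Without the number of BASAL957 these lists had 0 calls each in limma (9 and 4 at an unadjusted p under 0.05), and without that of BASAL959 they had 1 and 0 (8 and 6). Of 28 named calls, 4 passed in every alternative run, those of Fam221a, Gpr97, Neb and Pigz. Without the number of BASAL957, Il2ra stood at -1.10 (limma adjusted p = 0.146), and its call was lost in 3 of 31 alternatives in all.

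**Figure D4:**
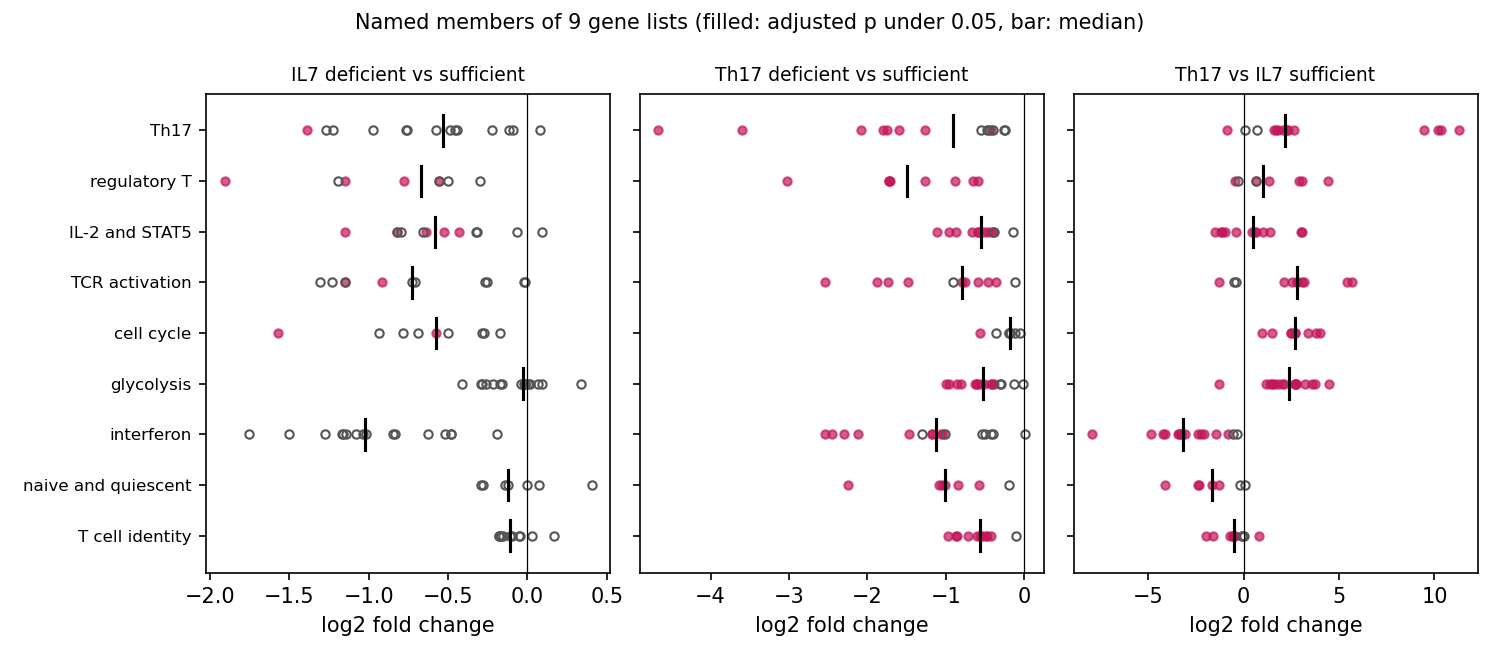
Log2 fold changes of the named members of 9 gene lists in 3 comparisons, 1 point per gene, filled where the limma adjusted p was under 0.05, with bars at the medians. In deficient Th17 cells the regulatory T cell list had its median at -1.49.

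Polarization itself was measured in sufficient cells by comparing Th17 with IL-7 libraries. The Th17 list rose in 11 of 14 cases, with Il22 (log2 change 11.29), Il21 (10.33), Il17f (10.21) and Il17a (9.46). Il22, Il21 and Il17a averaged 5.92, 4.06 and 2.91 normalized counts in sufficient IL-7 cells, so the size of their change depends on the pseudocount. The Il22 mean comes almost wholly from BASAL960 (22.8). Glycolysis genes rose in 15 of 16 cases, such as Tpi1 (4.47), Pgk1 (3.72) and Gapdh (3.21). All 9 tested cell cycle genes rose, including the cyclin gene Ccnb2 (3.99) and Ube2c (3.78). Activation genes rose in 8 of 11 cases, with the immediate early gene Nr4a1 at 5.66, Fosl2 at 5.39 and Il2ra at 3.04. Regulatory T cell genes rose in 5 of 8, with Ctla4 at 4.42, and amino acid stress genes in 7 of 8, with Ddit4 at 4.03.

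Genes of the resting state fell over polarization in sufficient cells. The naive and quiescent list fell in 5 of 7 cases, with the egress receptor S1pr1 at -2.40, Pecam1 at -2.36 and Bcl2 at -1.66. Interferon genes fell in 14 of 16 cases, among them Rtp4 (-7.95) and Ifit1 (-4.12). T cell identity genes fell in 7 of 11 cases, and Th1 genes in 4 of 7, with the chemokine receptor Cxcr3 at -3.07 and Stat4 at -1.76. Gata3 fell by 1.84 on the log2 scale. The largest falls among genes passing the naming rule were Pyhin1, an interferon-inducible gene (-8.14), Rtp4 and Pdlim4 (-7.72). In all, 11236 of 14638 rows passed a limma adjusted p of 0.05, 5314 higher and 5922 lower. Against other named genes, glycolysis (limma camera adjusted p = 9.9e-06), cell cycle (0.00144), Th17 (0.00538) and activation genes (0.0235) lay higher, and interferon (0.00062), naive (0.0207) and T cell identity genes (0.0455) lower. None passed with an estimated correlation (each adjusted p = 0.62). The lists were drawn from genes that fell in deficient Th17 cells, and these counts share the sufficient Th17 libraries with that choice.

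Polarization was measured in deficient cells in the same way. The Th17 list rose in 10 of 14 cases, with Il21 at 10.63, Il22 at 9.14, Il17f at 8.63 and Il17a at 6.62. Glycolysis genes rose in 15 of 16 and cell cycle genes in 9 of 9, with Tpi1 at 3.83 and Ube2c at 5.17. All 7 tested naive genes fell, Pecam1 at -4.33, and all 16 tested interferon genes fell, Xaf1 at -6.35. T cell identity genes fell in 10 of 11 cases, with Cd3d at -1.31. Regulatory T cell genes rose in 3 of 8 and amino acid stress genes in 4 of 8 cases. In the interaction test below 3 members of each list were called lower, near the share over all named rows (2346 of 7007). In limma 11478 rows passed, 5500 higher and 5978 lower. Among the 7007 named rows 1979 were higher and 3529 lower, against 2839 and 2492 in sufficient cells. Named genes were listed for falling in these deficient Th17 libraries, so fewer rises and more falls follow in part from that choice. The glycolysis (limma camera adjusted p = 2.4e-07), cell cycle (1.8e-05), Th17 (0.00149), activation (0.00163), interferon (0.0119), naive (0.0138) and T cell identity lists (0.0207) stood apart from other named genes, and none did with an estimated correlation (adjusted p = 0.62 for 6 of them and adjusted p = 0.759 for interferon).

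Whether the deletion effect differed between both stages was tested as an interaction. The change in deficient cells was more negative at Th17 than in IL-7 cells for Tgfb3 (difference in log2 change -4.09), Il17a (-2.85), Tigit (-2.47), Pecam1 (-1.97), Ddit4 (-1.76), Fosl2 (-1.62), Satb1 (-1.50), Tet1 (-1.40) and Cdkn1b (-1.24). Il17f differed by -1.58 and Gata3 by -0.99. The T cell identity list had 8 of 11 members called lower (9 adjusted over the list alone), with Cd3d at -0.79. The difference was positive for the kinase gene Alpk2 (1.62), but rests on single reads in IL-7 cells, where its mean was 4.25 in sufficient and 0.247 in deficient cells. It was 0.22 with a pseudocount of 8 and did not pass, nor did it without the number of BASAL955 or BASAL957. Il22 (-2.16) and Il2ra (0.56) did not pass (limma adjusted p = 0.134 and 0.19). In all, 5437 of 14638 rows passed a limma adjusted p of 0.05, 2878 with a positive and 2559 with a negative difference. Among named rows, the only ones in the lists, 20 were positive and 2346 negative, since names exist only for genes that fell in Th17 cells. Against other named genes, T cell identity genes lay lower (limma camera adjusted p = 0.0207), and cell cycle (2.7e-05), interferon (0.0235) and IL-2 and STAT5 genes (0.0344) higher, none of them with an estimated correlation (adjusted p = 0.62, 0.62, 0.774 and 0.62). Without the number of BASAL957, 3269 rows passed, and Gata3 (-0.74) and Il17f (-1.60) did not. Gata3 also did not pass without the number of BASAL959, nor Il17f without that of BASAL955. In all the Il17f call was lost in 3 of 30 alternatives. The Il17a difference rests on single reads in IL-7 cells and did not pass with voom weights (-2.85, limma adjusted p = 0.36).

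The deletion effects at both stages, which share no library, were compared across the 14638 rows. Pearson's r was 0.320 and Spearman's rho 0.306 across genes, which are not independent replicates. Of 282 rows higher in IL-7 cells, 200 were also higher in Th17 cells, against 77.9 for independent lists, and of 332 lower rows 188 were also lower, against 93.1. Cenpa was called lower at both stages, though not in IL-7 cells without the number of BASAL957 or BASAL959. Il2ra was also called at both, but its change of -0.59 in Th17 cells (limma adjusted p = 0.0385) did not pass without any 1 of the 4 sufficient Th17 libraries, D3TAM955, D3TAM959 or D3TAM960, nor without the numbers of BASAL955, BASAL957 or BASAL959. Without the number of BASAL957, 10 rows were higher at both stages, against 2.76 for independent lists, and 9 lower, against 3.98.

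Genes that rise at least 2-fold over polarization were chosen in sufficient libraries of 2 replicate numbers and measured in the others, over all 6 choices. Their median change in deficient minus sufficient cells was -0.12 on the log2 scale, from -0.27 to 0.01 over the choices. For genes rising 4-fold it was -0.28 (-0.51 to -0.13), and for falling genes 0.056 (-0.026 to 0.17). The choices differed by the number of BASAL960. With it among the choosing libraries, the 2-fold genes gave -0.27 to -0.20, the 4-fold genes -0.51 to -0.36 and the falling genes 0.12 to 0.17. With it among the measured libraries, they gave -0.043 to 0.0099, -0.20 to -0.13 and -0.026 to -0.0067.

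The counted markers of other cell types took small shares of the reads. Only joined markers could be counted, 6 of 9 for B cells, 3 of 15 for myeloid, 2 of 7 for NK and 1 of 9 for erythroid cells. These 4 shares are therefore undercounts and do not measure purity. B cell genes took 0.0554% ± 0.00551 in sufficient and 0.0651% ± 0.00183 in deficient IL-7 cells, and 0.0039% ± 0.000944 and 0.00165% ± 0.000592 in Th17 cells (n = 4 each). Myeloid genes took 0.015% and 0.0118% in IL-7 cells, with 0.0212% in BASAL960 and 0.0117% to 0.0139% in the other sufficient libraries, and 0.00813% and 0.00525% in Th17 cells, and NK, CD8 and erythroid genes took under 0.00278% in every group mean. The 135 named rows of ribosomal protein genes took 6.60% ± 0.442 in sufficient and 5.65% ± 0.156 in deficient Th17 cells (n = 4 each). In 8 of 16 such comparisons, the mitochondrial and B cell shares in IL-7 cells among them, the two-sided exact permutation p was 0.0286, the lowest that 4 against 4 allows. The adjusted p of these was 0.0571, which is bounded by that floor and does not show that shares were equal. The counted markers and the named ribosomal and mitochondrial rows all come from genes listed for falling in deficient Th17 cells. A lower share there follows in part from that choice.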

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

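The explanations weighed in this part and the other splits of the libraries were tested only after the results had been seen. Single libraries lay far from the rest of their group in 6 of 68 groups examined, over read totals, detected rows, read shares and 7 genes, where chance gives about 1 in 20. The measure is the gap to the nearest library over the range of the group, set against Dixon's 95% critical value for 4 libraries. For Il22, BASAL960 was highest in sufficient IL-7 cells at 22.8 normalized counts (0.963). For Gata3, BASAL960 was highest among the same cells at 1278 (0.870), and D3955 was lowest in sufficient Th17 cells at 197.5 (0.833). For Sin3a, BASALTAM955 was highest in deficient IL-7 cells at 2358 (0.862). In deficient Th17 cells, D3TAM960 was highest for Il17a at 349.7 (0.835), and D3TAM955 was lowest for Il4 at 32.5 (0.8292).

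The effect of the deletion differed between the stages for 35 of the genes that these texts single out, by the interaction test of limma, and for 2366 of 7007 named rows in all (20 positive and 2346 negative). All differences here are log2 changes at Th17 minus those at IL-7. Among cytokine and effector genes they were Il17a (-2.85), Il17f (-1.58), Tgfb3 (-4.09), Gata3 (-0.99), Stat4 (-0.79), Smad3 (-0.72) and Prdm1 (-0.79, limma adjusted p = 0.04998). Receptor and activation genes were Tigit (-2.47), Fosl2 (-1.62), Tnfrsf4 (-1.47), Tnfrsf18 (-1.16) and Ctla4 (-0.95). Genes of the naive and quiescent state were Pecam1 (-1.97), Satb1 (-1.50) and Bcl2 (-0.75), and T cell identity genes were Cd3d (-0.79) and Thy1 (-0.67). Chromatin, cycle and metabolic genes were Tet1 (-1.40), Kdm5a (-0.81), Cdkn1b (-1.24), Ddit4 (-1.76), Trib3 (-1.47), Slc2a1 (-0.84), Pgk1 (-0.78) and Rpl22l1 (-1.49). Besides Tgfb3, the most negative differences among these genes were in Sncb (-4.47), Dhdh (-4.43), Kremen2 (-4.11), Myo16 (-4.05) and H2-Q10 (-3.90). Positive differences stood in Alpk2 (1.62), AA467197 (1.41), Ly6g5b (1.38), Fam19a3 (1.20) and Pdlim4 (0.97). With 30 alternatives, 21 of the 35 calls passed in each. Pdlim4 did not pass in 19 of them, Prdm1 in 18, Ly6g5b in 14, Pgk1 in 7, Bcl2 in 6, and 9 other genes in 1 to 3. With 1 library left out, Pdlim4 passed only without D3959, D3960 or D3TAM957, Prdm1 only without D3955, D3957, BASALTAM960 or D3TAM960, and Ly6g5b only without BASAL955, BASAL957, BASAL959, D3960, BASALTAM960 or D3TAM957. Pgk1 did not pass without BASAL955, BASAL959, D3960 or BASALTAM960, nor Bcl2 without D3957, D3960, BASALTAM955 or BASALTAM959. The Alpk2 difference rests on single reads in IL-7 cells and was 0.22 with a pseudocount of 8, where it did not pass. Named genes were listed for falling in Th17 cells, so negative differences had more room to appear.

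The fall of Il17a, Il17f and Il22 in deficient Th17 cells may reflect a direct need for Sin3A in cytokine expression, or fewer polarized cells, or the treatment. A share of 0.282 would explain Il17f alone, and rows that rise 4-fold over polarization would then have medians of -1.47 to -1.34. Their median difference was -0.28 over 6 choices of libraries, from -0.51 to -0.13, a smaller fall. In every choice the observed median lay above the expected one, and 19.4% to 26.3% of the rows lay at or below the expectation. This argues against a share of 0.282, with the other cells left as in IL-7, as the whole cause for these rows. The rows spread widely (SD 1.31 to 1.49), which describes single rows and not the precision of their median. Glycolysis and cell cycle genes also rise over polarization. A milder loss of polarized cells, or fewer cytokine producers among activated cells, is therefore not excluded. Tamoxifen itself stays open, because 0 libraries had tamoxifen without the floxed alleles.

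In IL-7 cells, lower interferon, IL-2 and STAT5, and regulatory T cell genes could come from BASAL960, the least similar of the 4 sufficient IL-7 libraries to its group, with a mean correlation of 0.981. Without it the median change of the interferon list went from -1.03 to -0.34, which is consistent with this library as the source of most of that fall. The medians of the other lists stayed at -0.44 (IL-2 and STAT5) and -0.60 (regulatory T cells), which argues against it as their whole cause. An effect of the deletion or of tamoxifen on these lists remains possible, and these cannot be separated in this design.

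Other splits of the same libraries were compared with the real grouping. In fits on the 8 libraries of a comparison, 1 of 35 splits, the real one, gave as many called rows as the labels. The real counts were 578 (deletion in IL-7), 7737 (deletion in Th17), 10499 (polarization in sufficient cells) and 11199 (polarization in deficient cells), and the highest count of another split was 0 in each with limma. At an unadjusted p under 0.05 the real splits gave 2915, 8382, 10794 and 11330 rows, and the highest other splits 2060, 1987, 2511 and 801. Taking the libraries as unpaired, the real split ranked first by either count, a share of 1 in 35, the smallest that these splits can give. In 46 of 48 cases, however, a library's deviations correlated best with its own number in another group. Only splits that part every same-number pair respect such pairing. They are fewer, so the smallest share is then larger, and these splits do not exclude chance. The IL-7 count was also not stable. In the fit on all libraries it went from 614 to 30 without the number of BASAL957 and to 114 without that of BASAL959. With 1 library left out it was 328 without BASAL957, 304 without BASALTAM955, 237 without BASALTAM957 and 362 without BASALTAM959. For the interaction, 3 of 100 drawn splits, the real one included, gave as many rows, with 5437 for the real and 5848 for the highest other split. The pair of splits above the real one kept the true Th17 groups and exchanged 2 IL-7 libraries each way, which points to the Th17 difference as the structure behind the count. A further draw that kept the Th17 groups and exchanged 1 IL-7 library each way gave 5228. Draws that mixed the Th17 groups gave at most 3. The share of 3 in 100 therefore follows the Th17 difference and does not test whether the effect differs between stages.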

How the results depend on the processing

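The alternatives on pseudocounts, unsettled rows, voom weights, library weights, and single left-out libraries for the correlation and the read shares were chosen after seeing the data. The number of rows called in IL-7 cells moved most. It was 936 with the replicate block (among them 7 IL-2 and STAT5, 5 regulatory T cell, 4 activation, 3 Th17, 3 cholesterol and 2 interferon genes), 2622 with library weights, and 30 to 735 when libraries were left out. The planned quasi-likelihood and Wald tests on counts and the TMM scaling were not run on the restored reads, for which voom weights were the only count-based alternative. The interaction called 3269 to 5891 rows when libraries were left out. In the other fits the interaction, and in all fits the Th17 deletion and both polarization counts, stayed within 1.5 times of the values given. Of 214 calls on named genes, 39 were lost without the number of BASAL957 and 37 without that of BASAL959, 13 without each of the other numbers, 11 with voom weights and 9 with 8-library fits. No call on a named gene reversed. Calls that passed in every alternative were 4 of 28 in IL-7 cells, 43 of 53 in Th17 cells, 49 of 50 and 47 of 48 over polarization in sufficient and deficient cells, and 21 of 35 in the interaction. The cause was not tested, beyond the smaller number of libraries.

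The Sin3a change in Th17 cells ran from -0.29 to -0.21 with libraries left out, and it no longer passed only without the number of BASAL957 (limma adjusted p = 0.0961, with 0.000932 the lowest over the alternatives). Over the alternatives the limma adjusted p ran from 5.6e-06 to 0.181 for Il22 in Th17 cells, from 7.6e-05 to 0.146 for Il2ra in IL-7 cells, and from 3.9e-05 to 0.36 for the Il17a, from 0.00219 to 0.0602 for the Il17f and from 6.1e-05 to 0.0785 for the Gata3 difference between stages. Values that did not pass changed sign for Il17f in IL-7 cells (-0.59 to 0.19) and for Il22 in IL-7 cells (-0.65 to 1.15, and -0.17 with a pseudocount of 8), both at low counts there, and the cause was not tested. The 27 list calls fell to 0 with an estimated correlation. At that setting a correlation between genes, estimated for each list, replaces the preset 0.01. The correlation of the deletion effects was 0.286 to 0.327 with libraries left out and 0.366 in rows with a mean CPM of at least 10. The polarization genes gave -0.28 for rows rising 4-fold and 0.056 for falling rows. With unsettled rows kept, 781 rows were called in IL-7 cells, 8841 in Th17 cells and 5731 for the interaction.

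The library numbers were taken as names only. Deviations from the group means correlated between libraries with the same number at a median of 0.10 (0.017 to 0.435 in 24 pairs, 12 of them above 0.1) and between other libraries at 0.056 or less (72 pairs). Of 48 best matches 46 went to the own number, a hint that the numbers pair the libraries. The labels also give each number the same sex in every group, though they do not say that a number is a mouse. The main fits and the exact permutation tests left such pairing out. The replicate block lost none of the named calls. Depth limits genes of few reads, such as Il17a and Il22 in IL-7 cells, where a difference was not detectable at this depth.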

Other observations

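The comparison of rows by level in this part was chosen only after the results had been seen. Further lists fixed before the data were examined were lower in part in deficient Th17 cells. In the IL-2 and STAT5 list 10 of 12 members fell, 11 adjusted over the list alone, with Prdm1, the gene of the repressor Blimp-1, at -1.11 and the receptor chain Il2rb at -0.96. In the IL-6 and TGF-β list 3 of 6 fell, with the TGF-β signal transducer Smad3 at -0.67 and the feedback inhibitor Socs3 at -0.40, and 0 of 6 passed in IL-7 cells in limma (1 at an unadjusted p under 0.05). The Socs3 call in Th17 cells was lost in 3 of 31 alternatives, 1 of them with 1 library left out. Of the Bcl2 family 4 of 5 fell, 5 adjusted over the list alone, with Bak1 at -0.79. Of the p53 targets 2 of 4 fell, with the DNA repair gene Ddb2 at -0.37, and of the germline genes 2 of 3, with the meiotic cohesin gene Stag3 at -1.07. Oxidative phosphorylation genes fell in 4 of 10 cases, with the complex I gene Ndufa2 at -0.42. Ribosomal protein genes fell in 57 of 130 cases, 51 adjusted over the list alone, with Rpl22l1 at -1.36, and this list includes pseudogenes that can share reads with their parent genes.

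Some lists had few members to test. The chaperone gene Hsp90ab1, the 1 tested heat shock gene, stood at -0.03 in Th17 cells and rose by 1.77 over polarization in sufficient cells. Of the neuronal list 0 of 2 passed for the deletion in Th17 cells in limma, with 1 at an unadjusted p under 0.05. Among markers of other cells, 2 of 4 B cell, 2 of 2 myeloid, 1 of 1 NK, 1 of 2 CD8 (Cd8b1, -0.84) and 1 of 1 erythroid genes were lower in deficient Th17 cells. Of the mitochondrial genome 0 of 2 genes passed for the deletion in limma at either stage, with 1 at an unadjusted p under 0.05 in IL-7 cells and 0 in Th17 cells. Over polarization in sufficient cells 7 of 10 oxidative phosphorylation genes rose, with the ATP synthase gene Atp5b at 1.29. The fixed gene Il4 stood at 305 ± 165 normalized counts in sufficient and 46.6 ± 9.55 in deficient Th17 cells (n = 4 each), and was not tested because its values in IL-7 cells were not settled.

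Rows at a low level changed in another way than rows at a high level. Settled rows of 10 to 100 normalized counts in sufficient Th17 libraries had median log2 changes of -0.37 and -0.35 in deficient cells over both divisions of the 4 numbers, with the level taken in libraries other than those measured. Rows of 100 to 1000 had medians of 0.071 and 0.061. With unsettled rows included the low rows stood at -0.35 in both. Genes rising in deficient Th17 cells carry no names here, so what they do was not analysed here.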
